A study of Homo sapiens with 2 samples.

How the data were processed

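Total RNA from 5637PR cells was profiled on 2 Affymetrix expression arrays, 1 hybridised with RNA of cells given the mock siRNA (si-mock) and 1 with RNA of cells given the siRNA against TNFAIP2 (si-TNFAIP2). Per the labels' protocols, RNA was isolated with RNAiso Plus, labelled with biotin and hybridised by the manufacturer's procedures. The background correction, the summarisation of probes and the normalisation between arrays are not given in the sources used here.

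The deposited table holds log2 expression values for 39029 probe sets on each array, as single numbers without detection calls. The log base was read from the values themselves, which run from 4.13 to 13.3 and exceed what a natural or base 10 logarithm of scanner intensity could reach. The sorted values of the 2 arrays differed by a median of 0.00613 and by at most 0.12, so the arrays had been brought to nearly one distribution before deposit. The lowest value corresponds to a linear intensity of 17.5. Where a constant was added before the logarithm, differences of dim genes are compressed, and whether one was added is unknown. The difference between the arrays was exactly 0 for 1746 probe sets (4.47%).

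Probe sets were named from the platform annotation supplied with the table, which names 15054 of the 39029 probe sets, each with 1 gene. The remaining 23975 probe sets are unnamed here, which does not mean that they lack a gene. All 15054 symbols matched the RefSeq gene table of assembly GRCh38.p14 through their Entrez identifiers. Probe positions and the genome build behind them are not given in the sources used here, so no coordinates are printed. TNFAIP2, CDH1 and CDH2 were not among the named probe sets and were not analysed here.

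The choices in this paragraph and the lists and naming rule that follow were made before the data were examined. The deposited log2 values were used unchanged. A gene took the probe set with the highest mean over both arrays, and 588 of the 14105 named genes had more than 1. A gene was kept when the higher of its 2 values reached 5.00, the median of all probe sets over both arrays, which left 9766 genes. The difference was taken as si-TNFAIP2 minus si-mock. With 1 array per group no test across replicates can be made and no p-value is given, so genes were called by size alone, at 2-fold for single genes and at 1.5-fold for members of gene lists. The planned design treated TNFAIP2 as the first result, and this value could not be obtained.

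There were 24 gene lists fixed in advance besides the target: epithelial, mesenchymal and transcription factor lists for the epithelial-mesenchymal transition (EMT), lists for signalling, stress, proliferation, platinum handling, urothelial differentiation and metabolism, markers of leukocytes, endothelial cells and fibroblasts, and 2 control lists of housekeeping and ribosomal protein genes. Of their 667 distinct genes including TNFAIP2, 409 were named and 365 were past the floor. For each list with at least 3 such members, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these 2 arrays. Genes are not independent replicates, and the percentile carries no information on the spread between cultures. The central 95% of random lists lies between percentiles 2.5 and 97.5. Of 23 lists with a percentile, 1.15 would be expected outside it by chance if the genes of a list varied independently. Genes that vary together put more lists outside.

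Genes are named in the text by a rule. It takes the 12 genes with the largest difference in each direction among those past the floor, leaving out uncharacterised loci, antisense RNAs, small RNAs, pseudogenes and genes whose probe sets differed in sign. It adds up to 4 genes with the largest absolute difference per list, up to 8 for the 3 EMT lists, and a fixed set of EMT genes (CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, ZEB2 and TWIST1). Genes named outside the rule are identified as chosen after their values were seen.

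The precision of a single difference was gauged in 2 ways, neither of which replaces biological replicates. Among genes of like mean expression, the local spread (1.4826 times the median absolute deviation, 20 bins) had a median of 0.177 on the log2 scale and ranged from 0.122 to 0.203. Between probe sets of the same gene, over 271 genes with several, leaving out chromosome 6, where many genes have repeated probe sets, the pooled standard deviation of the difference was 0.168. The number of arrays limits the precision.

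The alternatives were centring each array on its median, quantile normalisation, removal of a lowess trend of the difference on the mean (span 0.3), the mean over all probe sets of a gene, no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, a difference beyond 3 times the local spread, and the mean in place of the list median. An alternative with 16 subtracted on the linear scale before the logarithm was added after seeing the data. The scripts were tested on simulated data of 9766 genes, with normal noise of the local spread of these arrays, drawn independently for each gene. Of genes changed by 1.5 on the log2 scale, 100% in each direction passed 2-fold. Of genes changed by exactly 2-fold, 40% of the higher and 42% of the lower passed 2-fold and 100% passed 1.5-fold. Of 9566 unchanged genes, 0% passed 2-fold and 0.0836% passed 1.5-fold. These rates follow from the simulated noise and are not error rates of these arrays. The noise held no difference between cultures. In the real data more genes lay beyond 3 times the local spread than a normal distribution gives. Of 100 simulated lists of 25 genes shifted by 0.2, 99 lay above the upper limit of random lists, against 68 with a shift of 0.1 and 2 with no shift. For lists of 12 genes these numbers were 96, 44 and 5. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.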

Results

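The study examined how loss of TNFAIP2, a gene first described as induced by tumour necrosis factor (TNF), relates to EMT in platinum-resistant bladder cancer cells. 5637PR is a platinum-resistant derivative of an established human bladder carcinoma cell line. Expression was measured on 1 array of cells transfected with a mock siRNA and on 1 array of cells transfected with an siRNA against TNFAIP2. All values are log2 expression values of single arrays, and there were no replicates, so differences describe these 2 arrays. The medians were 4.997 on the si-mock array and 5.003 on the si-TNFAIP2 array, and the arrays correlated at r = 0.992 across 39029 probe sets. TNFAIP2 itself was not among the named probe sets, so the knockdown was not checked here and the direction of each difference rests on the sample labels.

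Few genes differed by 2-fold or more between the arrays as deposited, while 29 higher and 38 lower did with 16 subtracted before the logarithm. Among 9766 named genes past the expression floor, 5 were at least 2-fold higher with si-TNFAIP2 and 8 were at least 2-fold lower, and 98.3% lay within 1.5-fold. The highest was CCL20, the chemokine ligand of CCR6, at 6.47 with si-mock and 8.04 with si-TNFAIP2, a 2.98-fold difference. CSF3, which encodes granulocyte colony-stimulating factor, was 2.07-fold higher and already abundant with si-mock at 9.75. The other genes past 2-fold were ZNF107, a zinc finger gene (2.06-fold), OLR1, the oxidised LDL receptor (2.03-fold), and STC1, the secreted hormone stanniocalcin (2.03-fold).

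Below 2-fold, the genes with the next higher values past the floor on both arrays were IL11, a cytokine of the interleukin-6 family (0.88 on the log2 scale), ZNF138 (0.84) and ARRDC3, an arrestin-domain adaptor (0.84). CXCL8, the neutrophil chemokine interleukin-8, was 1.75-fold higher. KYNU, an enzyme of tryptophan breakdown, was 1.73-fold higher, and SCML2, a polycomb group gene, was 1.71-fold higher. EOLA1-DT, a non-coding transcript, was below the floor with si-mock (4.61) and past it with si-TNFAIP2 (5.50), and its difference was 1.80 on the log2 scale with 16 subtracted. ZNF107 and ZNF138 belong to a family of closely related zinc finger genes whose probes could cross-hybridise.

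The 8 genes past 2-fold in the other direction were led by ANKRD1, an ankyrin repeat gene and well-known target of the YAP coactivator, which was 6.50 with si-mock and 5.23 with si-TNFAIP2, a 2.41-fold difference. TMEM200A was 2.34-fold lower. SSB, which encodes the RNA-binding La protein, was 2.19-fold lower. CRIM1, a transmembrane protein that binds bone morphogenetic proteins, was 2.18-fold lower from 9.10. MTDH, which encodes metadherin, was 2.16-fold lower. COX7C, a subunit of cytochrome c oxidase, was 2.10-fold lower. LIN7C, a polarity scaffold, and SCPEP1, a serine carboxypeptidase, were each 2.05-fold lower. Close to 2-fold lay KRTAP2-3, a keratin-associated protein of a near-identical gene group (5.47 with si-mock and 4.47 with si-TNFAIP2), FLRT3 (7.26 and 6.26), TMTC3 (8.03 and 7.03) and PEBP1, the RAF kinase inhibitor protein (8.14 and 7.16).

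At 1.5-fold, 51 named genes were higher and 111 lower, so 68.5% of these were lower. With 16 subtracted before the logarithm, 177 were higher and 291 lower (62.2% lower). Transcripts that the siRNA lowers off target were not separated here from those that follow TNFAIP2, for the genes named above as for these counts. The split did not extend to the probe sets without a gene name, of which 109 were at least 1.5-fold higher and 68 lower. Over all 20419 probe sets past the floor, 164 were higher and 186 lower. Beyond 3 times the local spread lay 93 higher and 160 lower named genes, where a normal distribution would give 26.4 in all.

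**Figure D1:**
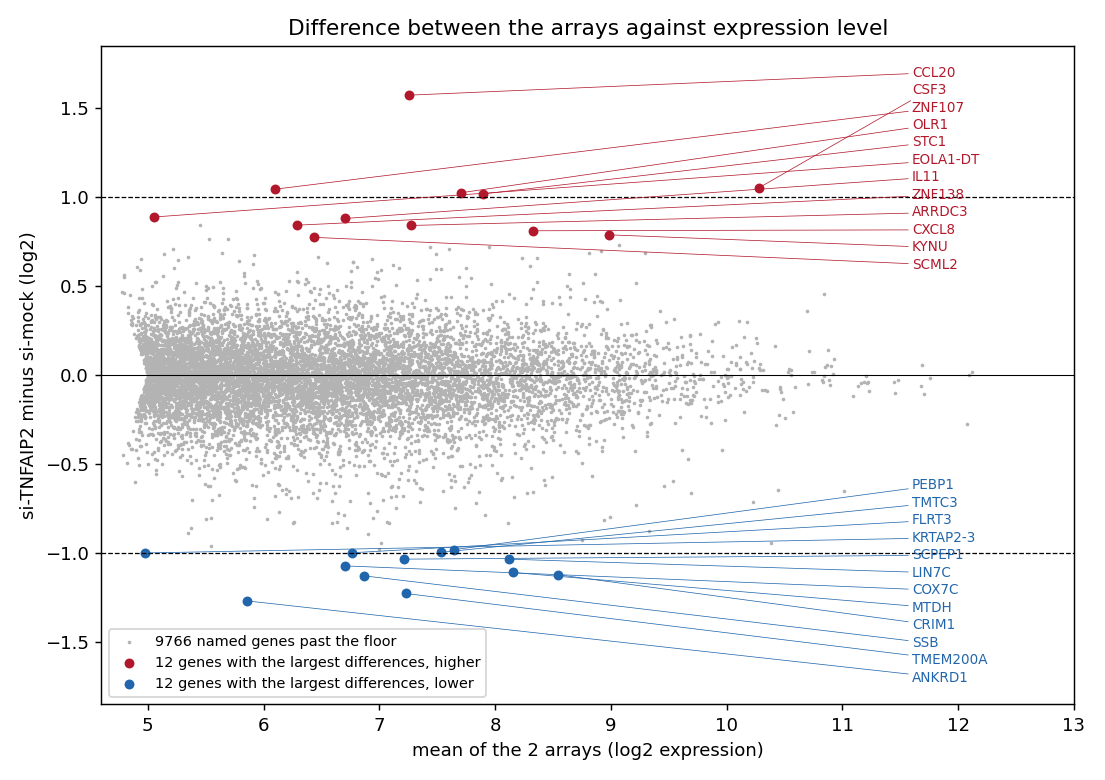
Each grey point is 1 of 9766 named genes past the floor, with the mean of the 2 arrays (log2 expression) on the x axis and si-TNFAIP2 minus si-mock (log2) on the y axis; red and blue points are the 12 genes with the largest difference in each direction and dashed lines mark 2-fold. CCL20 stands highest at 1.57 and ANKRD1 lowest at -1.27, and 98.3% of genes lie within 1.5-fold.

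The comparison the study was designed for concerned EMT, the change in which epithelial cells lose junctions and take on mesenchymal features. None of the 3 EMT lists stood apart from random lists of like expression. Of 29 epithelial genes past the floor, 1 was at least 1.5-fold higher, 0 were 1.5-fold lower, and the median difference was -0.018 (percentile 39.9). Of 18 mesenchymal genes, 0 reached 1.5-fold in either direction, and 13 lay below 0 and 5 above, with a median of -0.068 (percentile 11.3), or -0.027 without the floor. Of 13 EMT transcription factors, 0 reached 1.5-fold, with a median of -0.036 (percentile 31.8), or 0.0010 with the higher floor. With 16 subtracted before the logarithm, which stretches dim genes, 3 epithelial genes were 1.5-fold higher, CLDN4 (0.72 on the log2 scale) among them. In that setting 2 epithelial genes, OCLN (-0.63) and TJP3 (-0.61), and 1 transcription factor, TWIST1 (-0.63), were 1.5-fold lower. The list medians stayed inside the random range. The central 95% of random lists ran from -0.085 to 0.054 for the epithelial list and from -0.106 to 0.072 for the mesenchymal list. Small shared shifts could be missed, since a simulated shift of 0.1 put 68 of 100 lists of 25 genes and 44 of 100 lists of 12 genes above the upper limit.

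Single epithelial genes went both ways. The desmosomal cadherin DSC2 was 1.51-fold higher, the tight junction gene CLDN4 1.43-fold higher and the polarity gene CRB3 1.26-fold higher. Keratin KRT19 was 1.41-fold lower, the membrane protease ST14 1.39-fold lower, and KRT7 1.27-fold lower. The tight junction genes OCLN and TJP3 were past the floor with si-mock, at 5.34 and 5.31, and just below it with si-TNFAIP2. In units of the local spread, the furthest of these genes were CLDN4 (3.17), DSC2 (3.165), KRT19 (-2.84) and OCLN (-2.84).

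Of the mesenchymal genes, VIM, the intermediate filament vimentin, was 7.71 with si-mock and 7.66 with si-TNFAIP2. FN1, the matrix protein fibronectin, was 10.15 and 10.27. The largest differences were in FBN1 (-0.30), THY1 (-0.30), THBS1 (-0.27), TPM2 (-0.23), TPM1 (-0.22, or -0.12 as the mean of its 2 probe sets), TIMP1 (-0.20), AXL (-0.13) and CD44 (0.13). Every one of these lay within 2 times the local spread of genes of like expression. The collagens, the integrins ITGA5, ITGAV and ITGB3 and the matrix metalloproteinases MMP2, MMP3 and MMP9 of the list were not among the named probe sets and were not analysed here, nor were CDH1 and CDH2.

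Among EMT transcription factors, SNAI2 (Slug) was abundant, at 10.63 with si-mock and 10.39 with si-TNFAIP2. TWIST1 was 5.50 and 5.13, close to the floor. ZEB2 was 4.99, below the floor, and 5.29. SNAI1 (4.72 and 4.94) and ZEB1 (4.87 and 4.94) were below the floor on both arrays. HMGA2, a chromatin architectural factor, was 1.32-fold higher and SOX4 1.23-fold higher. TCF4 was 1.23-fold lower. LEF1 was 5.50 and 5.18, close to the floor, and GSC was 5.21 and 4.92, below the floor with si-TNFAIP2. Beyond 2 times the local spread lay HMGA2 (2.62), ZEB2 (2.27), SOX4 (2.11), TWIST1 (-2.26) and GSC (-2.20).

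Genes induced by TNF and the transcription factor NF-kB were higher as a group. Of 41 listed genes 28 were named and 25 were past the floor. NFKBIA, TNFAIP3, IL6 and BIRC3 were not among the 25. Of these 25, 5 were at least 1.5-fold higher, 0 were 1.5-fold lower, and 21 lay above 0. The median difference was 0.20 on the log2 scale, above the medians of all 10000 random lists. The 5 were CCL20, CSF3, CXCL8, CXCL2 (1.55-fold) and CXCL6 (1.54-fold), all secreted chemokines or growth factors. CXCL6 and the members named next were chosen after their values were seen. CXCL5, at 10.61 with si-mock, was 1.37-fold higher, and LIF, a cytokine of the interleukin-6 family, was 1.42-fold higher. NFKB1, which encodes the p50 precursor, was 1.33-fold lower, and CXCL3 was 1.16-fold lower. Other members that are not secreted stayed within 1.5-fold. So did further secreted members, SAA1 (0.095 on the log2 scale), CCL5 (0.12), LCN2 (0.26) and CSF1 (0.27), so secretion did not separate the raised members. On the log2 scale NFKB2 and IRF1 differed by 0.37 each, ICAM1 by 0.037, RELB by 0.076, PTGS2 by -0.063 and BIRC2 by -0.15. CXCL2 and CXCL3 are near-identical paralogs, so probes may not separate them fully. The list's mean difference was 0.30.

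Immediate-early and ERK feedback genes were also higher as a group. Of 18 members, 15 lay above 0, 1 was at least 1.5-fold higher and 0 were 1.5-fold lower, with a median of 0.22, again above all 10000 random lists. HBEGF, a ligand of the EGF receptor, was 1.62-fold higher and EREG, another such ligand, 1.42-fold higher. EGR1, an immediate-early transcription factor, was 1.40-fold higher, and 0.24 on the log2 scale higher as the mean of its 2 probe sets. SPRY2, a feedback inhibitor of the pathway, was 1.32-fold higher. MYC was 1.22-fold lower. The immediate-early genes JUN (-0.13 on the log2 scale), IER2 (-0.0072), FOS (0.023, near the floor) and FOSL1 (0.061) differed little, while FOSB differed by 0.26. MYC and these genes were chosen after their values were seen. IER3 belongs to both this list and the TNF list.

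Targets of the YAP coactivator and its TEAD partners were lower as a group. Of 21 listed genes 12 were named, all past the floor. All 12 lay below 0, 3 of them at least 1.5-fold, with a median of -0.21 (percentile 0.12) and a mean of -0.39. The 3 were ANKRD1, CRIM1 and CCN2, which encodes connective tissue growth factor and was 1.52-fold lower. AJUBA, a LIM-domain scaffold, was 1.32-fold lower. CCN2 also led the lower members of the TGF-beta list.

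**Figure D2:**
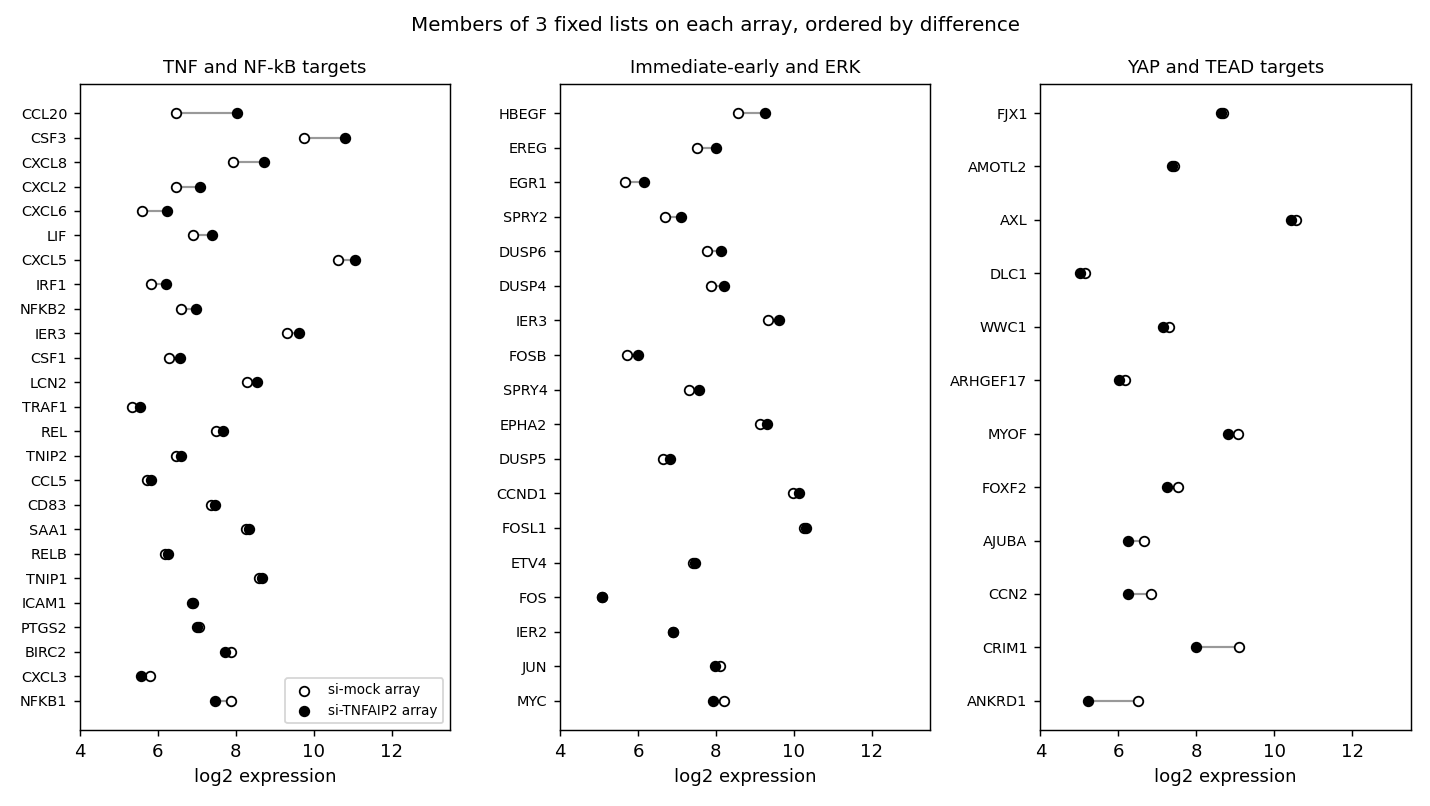
Each row is a gene of the TNF and NF-kB list, the immediate-early and ERK list or the YAP and TEAD list, ordered by difference, with its log2 expression on the x axis; open circles are the si-mock array and filled circles the si-TNFAIP2 array. In the YAP and TEAD list all 12 filled circles lie to the left, while 21 of 25 and 15 of 18 lie to the right in the other lists.

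Of the urothelial differentiation lists, the basal list lay below the random range and the luminal list inside it. Of 12 basal and squamous genes, 9 lay below 0 and 1 was at least 1.5-fold lower, with a median of -0.14 (percentile 1.06). DSC3, a desmosomal cadherin, was 1.60-fold lower, and the basal keratin KRT5 1.27-fold lower. KRT16 was 5.43 and 5.16, close to the floor, and TRIM29 was 5.03 and 4.80, below the floor with si-TNFAIP2. This list fell inside the random range in 2 of 8 alternative settings. Of 12 luminal genes, 0 reached 1.5-fold and the median was 0.046 (percentile 87.3), or -0.089 with the higher floor. ERBB3 was 1.21-fold higher, GATA3 1.16-fold lower and KRT18 1.15-fold lower (-0.21 on the log2 scale, or -0.10 as the mean of its 2 probe sets), and FOXA1 was 4.93, below the floor, with si-mock and 5.16 with si-TNFAIP2.

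Platinum handling, stress and survival lists lay within the random range, as far as their members were past the floor. The platinum members past it were metallothionein and glutathione transferase genes and XRCC1, so platinum transporters and other repair genes were not assessed. CDKN1A, MDM2, GADD45A and BTG2 were not among the p53 genes past the floor. Of 35 genes in the platinum list 7 were past the floor and 0 reached 1.5-fold (median 0.034, percentile 74.7), and XRCC1, MT1F and MT1E differed by 0.11, 0.12 and -0.17, while GSTM3 was 5.22 and 5.38, close to the floor. The p53 list had a median of 0.0065 (13 genes, percentile 69.1) and a mean of 0.083 (percentile 96.6). Its 1 member past 1.5-fold was PMAIP1, which encodes the pro-death protein NOXA and was 1.64-fold higher, followed by SESN2 (0.38), TIGAR (-0.32) and TRIAP1 (-0.32). In the apoptosis list (19 genes, median 0.066, percentile 96.5), PMAIP1 was higher and FADD, the death receptor adaptor, was 1.55-fold lower, though under 1.5-fold as the mean of its 2 probe sets (-0.48 on the log2 scale), while MCL1 was 1.36-fold and CFLAR 1.31-fold higher. The NRF2 list had a median of -0.0061 and a mean of 0.041 (11 genes, percentile 54.7 for the median), with TXNRD1 1.37-fold higher and GSR and HMOX1 at -0.18 and 0.14, while OSGIN1 was 5.20 and 5.40, close to the floor.

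The unfolded protein and ATF4 list had a median of 0.035 (15 genes, percentile 85.6), or 0.081 with the higher floor, and a mean of 0.080 (percentile 97.1). Its member past 1.5-fold was DDIT4, a stress-induced inhibitor of mTOR signalling, which was 1.54-fold higher, and ASNS differed by 0.26. CTH was 5.04 with si-mock and 4.81, below the floor, with si-TNFAIP2. Interferon-stimulated genes had a median of 0.0012 and a mean of -0.021 (21 genes, percentile 65.6 for the median) with 0 members past 1.5-fold, and the largest differences were in IFITM2 (-0.30), IFITM1 (-0.29), SAMD9 (-0.26) and IRF9 (0.24). TGF-beta targets had a median of 0.09 and a mean of -0.013 (11 genes, percentile 96.0 for the median, which was -0.099 with the higher floor), with TGIF1 1.44-fold higher, CCN2 lower and SKIL 1.17-fold lower. ANGPTL4, dim at 5.66 and 5.29, differed by -0.37, or by -0.58 with 16 subtracted.

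Growth and metabolic lists also lay within the random range. Of 40 proliferation genes, 0 reached 1.5-fold and the median was -0.058 (percentile 9.82). E2F1 was 1.39-fold higher, whereas MCM6, CDC20 and BUB1 were 1.28-fold, 1.25-fold and 1.23-fold lower. Cholesterol synthesis genes had a median of -0.094 (15 genes, percentile 9.98), with MSMO1, ACAT2 and MVK 1.46-fold, 1.33-fold and 1.33-fold lower and INSIG1 1.44-fold higher. Hypoxia and glycolysis genes had a median of -0.029 and a mean of 0.020 (13 genes, percentile 42.6 for the median), with NDRG1 1.44-fold higher and HK2 and ADM 1.27-fold and 1.26-fold lower. BNIP3, dim at 5.61 and 5.23, differed by -0.38, or by -0.60 with 16 subtracted. Genes of the exocyst, tunnelling nanotubes and filopodia, in which the TNFAIP2 protein is known to act, had a median of -0.043 (21 genes, percentile 27.1). On the log2 scale EXOC8 differed by -0.40, EXOC6 by -0.25, EXOC5 by 0.20 and LST1, which was dim, by 0.26, or by 0.43 with 16 subtracted.

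The control lists lay near 0. Their members ranged widely in signal, from RPL30 at 5.84 and GAPDH at 6.50 to RPL12 at 11.71 with si-mock. Differences of the dim members may be compressed, so they are a weak check of stability. Housekeeping genes had a median of 0.0026 and a mean of -0.014 (13 genes, percentile 68.3 for the median), with HPRT1, PPIA, GPI and VPS29 at -0.17, -0.12, -0.12 and 0.10. Cytosolic ribosomal protein genes had a median of -0.038 (34 genes, percentile 26.2), the largest differences being RPS29 (-0.22), RPS23 (-0.20), RPL27 (-0.16) and RPS14 (-0.15).

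Markers of other cell types were few past the floor. The 4 leukocyte markers had a median of 0.046 and a mean of -0.045 (percentile 76.3 for the median). LAPTM5 was high on both arrays, at 10.88 and 10.98, CD68 was 6.78 and 6.91, CD4 was 5.20 on both, and CD8A was 5.70 and 5.30. CD53 and CD14 were below the floor. The 3 endothelial markers had a median of -0.35 (percentile 0.755), from ERG (-0.35), ENG (-0.35) and CLDN5 (0.04), and without the floor the median was -0.15. Their mean was -0.22, inside the range of random lists (percentile 5.19). The 2 fibroblast markers, THY1 (-0.30) and FBLN1 (0.049), had a median of -0.13 and were too few for a percentile. In all, 5 of 23 lists lay outside the central 95% of random lists, against 1.15 expected by chance if the genes of a list varied independently.

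**Figure D3:**
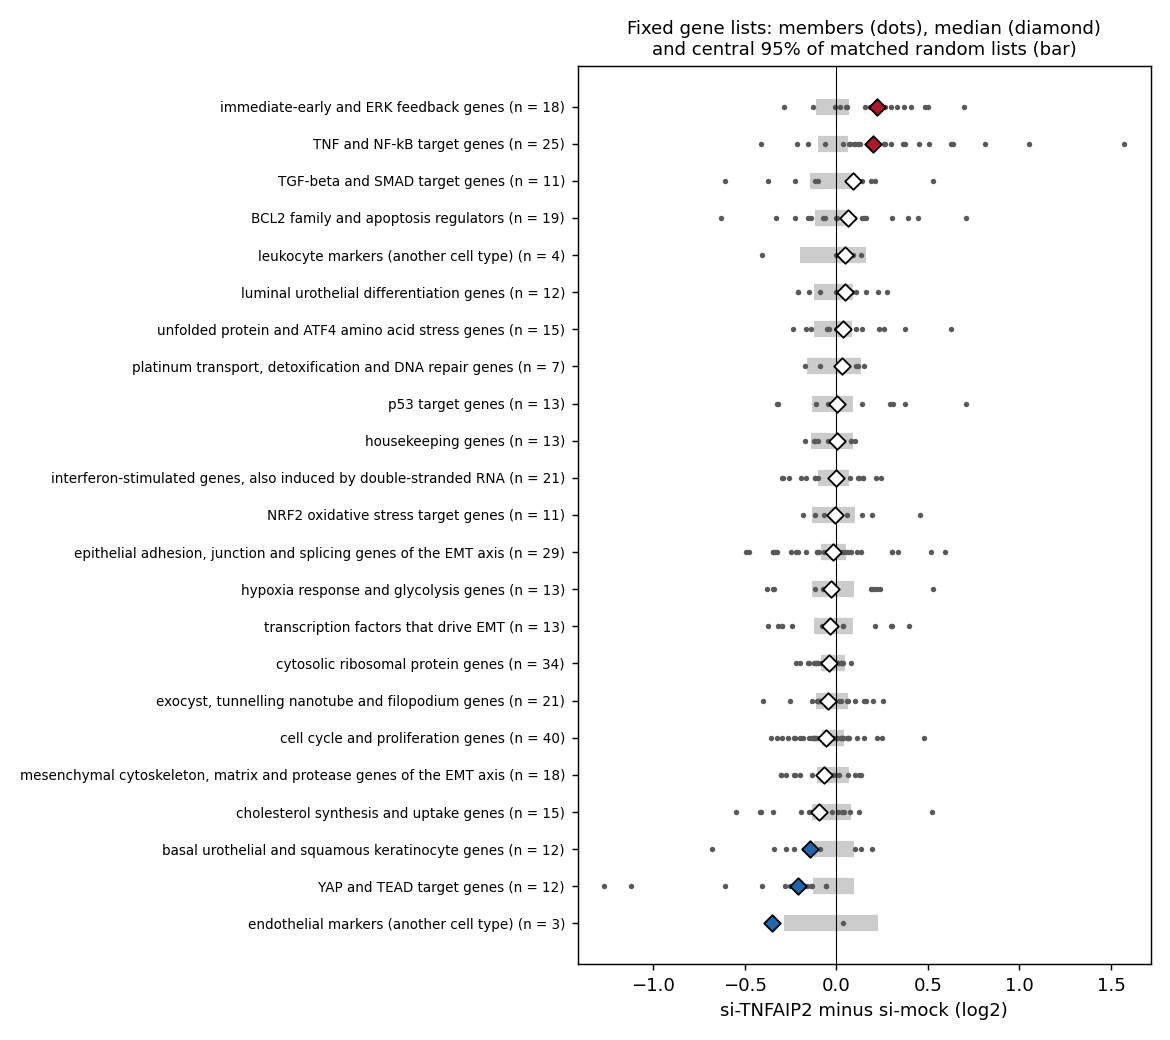
Each row is a fixed gene list with at least 3 members past the floor; dots are members, diamonds the median of si-TNFAIP2 minus si-mock (log2, x axis) and grey bars the central 95% of random lists of the same size and like expression. Red and blue diamonds lie outside the bar and white diamonds inside it: the TNF and NF-kB (0.20) and ERK (0.22) lists above it, and the basal (-0.14), YAP and TEAD (-0.21) and endothelial (-0.35) lists below it.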

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

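Among the 23975 probe sets without a gene name, which entered no gene list and no count of named genes, 10065 were past the floor. Of these, 6 were at least 2-fold higher with si-TNFAIP2 and 3 at least 2-fold lower. Their differences reached 1.40 and -1.11 on the log2 scale, within the range of named genes. Of the unnamed probe sets past 1.5-fold, 38.4% were lower, against 68.5% of named genes and 53.1% of all probe sets past the floor. Among named genes that are not protein-coding, 10 were higher and 7 lower at 1.5-fold, and among protein-coding genes 41 were higher and 104 lower. In 4 equal groups of named genes from the lowest to the highest mean signal, 41.2%, 78.1%, 74.1% and 66.1% of those past 1.5-fold were lower, with 10 higher and 7 lower in the dimmest group.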

How the results depend on the processing

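With 1 array per group no array could be left out, no paired analysis was possible because the groups share no replicates, and TNFAIP2 gave no value under any setting. The count of genes at least 2-fold different stayed at 5 higher and between 8 and 11 lower under centring, quantile normalisation, removal of the lowess trend, the mean over probe sets and both other floors, and the 5 and 8 genes of the main setting were kept in each of these. Other thresholds gave 51 higher and 111 lower at 1.5-fold, 0 and 0 at 3-fold, and 93 and 160 beyond 3 times the local spread. Subtracting 16 before the logarithm, chosen after seeing the data, gave 29 higher and 38 lower, as it stretches dim genes, with EOLA1-DT (1.80) above CCL20 (1.77) and KRTAP2-3 (-2.19) below ANKRD1 (-1.79). The medians of the 3 EMT lists moved by less than the spread of random lists and stayed inside the random range in all 8 alternatives. The TNF and NF-kB, ERK, and YAP and TEAD lists stayed outside it in all 8, with medians from 0.16 to 0.28, from 0.18 to 0.24 and from -0.26 to -0.20 and means of 0.30, 0.21 and -0.39. For these and the EMT lists, several of the 8 were weak checks. Centring shifts listed and random genes alike, and random lists were already matched on level. Centring, quantile normalisation, trend removal and the mean over probe sets each left 23 of 23 list medians within the spread of random lists. The basal list stayed outside in 6 of 8 and the endothelial list in 6 of the 7 that gave a percentile, as the higher floor left it too few members, and the apoptosis list lay outside in 1 of 8. Over all lists, 172 of 184 alternative medians or means moved by less than the spread of random lists and 12 moved by more, and the cause was not tested. With the higher floor the TGF-beta median turned from 0.090 to -0.099, the luminal median from 0.046 to -0.089 and that of the EMT transcription factors from -0.036 to 0.0010. The interferon, NRF2, hypoxia and housekeeping medians, all close to 0, also changed sign in at least 1 alternative. Of 827 alternative differences of named genes, 799 moved by less than the local spread and 28 by more, 27 of these with 16 subtracted. The 799 say little about stability. The floors, with 122 and 95 of the differences, cannot change a gene's value. The mean over probe sets cannot change a gene with 1 probe set, and centring shifts all genes alike. With 16 subtracted, 27 of 122 moved by more than the local spread. No list outside the random range and no named gene past 1.5-fold changed sign in the alternatives run for it. The pseudocount and the probe sets marked for cross-hybridisation were not run, since the table is on a log scale and its identifiers carry no such mark. Signal near the floor limits EOLA1-DT, KRTAP2-3, ZEB2, GSC, OCLN, TJP3, FOXA1, TRIM29 and CTH, each below it on 1 array, and TWIST1, LEF1, KRT16, LST1, BNIP3, ANGPTL4, CD8A, OSGIN1, GSTM3 and CLDN5, whose differences grew over 1.5 times with 16 subtracted. EGR1, KRT18, TPM1 and VIM shrank as much as the mean over probe sets.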

Other observations

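All tests of explanations in this part were chosen after the results were seen. Gene families defined by a shared symbol root, with at least 15 members past the floor, were placed among random lists as the fixed lists were. Of 58 families, 8 lay outside the central 95%, against 2.9 expected by chance if the genes of a family varied independently. Genes of the mitochondrial ribosome were lower with si-TNFAIP2. Of 51 MRPL genes 45 lay below 0 (median -0.13, percentile 0.01), and of 25 MRPS genes 21 (median -0.14, percentile 0.22), although only 1 of the 76 was at least 1.5-fold lower. METTL methyltransferase-like genes (median -0.16, 16 of 21 below 0) and NUDT hydrolases (-0.15, 14 of 20) were also lower, and both lay outside the random range in all 7 alternative settings. Keratins were lower (-0.18, 11 of 17 below 0), but were outside the range in only 5 of 7 settings, with a median of 0.014 without the floor and -0.10 (percentile 2.85) as the mean over probe sets. KDM lysine demethylases were higher (0.11, 13 of 18 above 0), outside the range in 6 of 7 settings and inside it without the floor. The remaining families, MAP (0.070) and TMEM (-0.042), group genes by symbol alone and were outside in 6 and 3 of 7 settings.

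The genes named next were picked one by one after their values were seen, from those past 1.5-fold, and stand for no tested group. IRAK2, a kinase of interleukin-1 signalling, was 1.61-fold higher, SOCS1, a feedback inhibitor of cytokine signalling, was 5.31 with si-mock and 6.08 with si-TNFAIP2, and the protease inhibitor SLPI was 1.58-fold higher. DKK1, a secreted WNT antagonist, was 1.86-fold lower and the Notch ligand JAG1 1.93-fold lower from 10.85. DNMT1, the maintenance DNA methyltransferase, was 1.90-fold lower.

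A first pattern is the higher level of TNF and NF-kB targets. Its median was 0.203 after a lowess trend with signal level was removed, but this decides nothing about such a trend here or in the patterns that follow, since random lists were matched on level and the correction moved 0 of 23 lists beyond their spread. An interferon response to double-stranded RNA would be expected to raise interferon-stimulated genes. Of these, 0 of 21 were 1.5-fold higher and their upper quartile, 0.12, lay below the TNF list's median. This comparison is weak, since the TNF list was picked for its high median. The housekeeping list, with 0 genes 1.5-fold higher and an upper quartile of 0.040, met it too. The interferon list's own median was 0.0012 (percentile 65.6), so these 21 genes showed no shared rise. A response shared by both transfections would cancel in the difference and cannot be seen this way. IFIT1, IFIT2, MX1 and OAS1 were not among the 21. Chemokine induction by some route of the transfection stays open, as does an effect of losing TNFAIP2, since each siRNA was seen in a single array.

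A second pattern is the lower level of YAP and TEAD targets. The list median was -0.199 after the level trend was removed. It did not rest on a few strongly lower members alone, since without ANKRD1, CRIM1 and CCN2 the median of the other 9 was -0.162 (percentile 1.59). These targets are known to respond to cell density and spreading, and density was not among the labels, so a difference between the 2 cultures may account for it as well as the knockdown.

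Another pattern is the lower level of mitochondrial ribosomal protein genes. The joint median of MRPL and MRPS genes, joined after each was seen to be lower, was -0.135, and -0.125 after the level trend was removed. A loss of short abundant transcripts may lower cytosolic ribosomal protein genes alike, whose median was -0.0377, with 23 of 34 below 0 and a lower quartile of -0.101, above the joint median. The cytosolic list lay inside the random range (percentile 26.2). The COX genes had 16 of 20 below 0, a median of -0.091 (percentile 3.75, also inside the random range) and a lower quartile of -0.17. They cannot decide it, since a mitochondrial change could lower them as well as a loss of short transcripts. Such a loss stays open. A biological difference between the transfections and a difference between the 2 RNA preparations both stay open, as neither is replicated.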
